A study of Mus musculus with 35 samples.

How the data were processed

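Perigonadal adipose tissue of 35 mouse samples in 10 groups was measured on Affymetrix MG-U74Av2 arrays, 1 array per sample. Per the labels the deposited values are MAS5 signal intensities, on a linear scale, 1 per probe set; no software version, scaling target or detection call was used here. The values ran from 0.0125 to 39602. 13 arrays shared a 2% trimmed mean, as after scaling to a target, and 22 had other trimmed means, from 336 to 1679. The deposited experiment file of each array holds other values, settings of washing, staining and scanning written by the array software, and was used only for batches. A scanner type is given on 13 arrays, the later batch, which are those with the common trimmed mean, and not on the 22 earlier ones. The wash protocol was version 4 on every later and version 3 on 21 earlier arrays, and was not given on CL316243 replicate 1. The arrays were scanned on 13 days.

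Every array was scaled to a 2% trimmed mean of 250. Of 12488 probe sets 66 controls were left out and 12422 tested, of which 10833 had 1 gene symbol, 396 several and 1193 none, for 8251 distinct symbols. A pseudocount of 23, the 25th percentile of the scaled signals, was added before taking log2, so fold changes near the background are compressed and small changes of dim genes are not resolved. Pearson r between arrays ran from 0.812 to 0.980. Means and SDs of levels are of scaled signals.

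limma 3.58.1 in R 4.3.3 fitted 10 group means to all 35 arrays, with contrasts for 14 comparisons and eBayes with a mean-variance trend. p was adjusted by Benjamini-Hochberg within a comparison, and a probe set was called at an adjusted p under 0.05. In data simulated at these group sizes, 46 to 63% of known changes of log2 1 and 92 to 98% of log2 2 were recovered, and with 2 CL316243 arrays 31 and 87%. False calls were 2.03 to 7.64% of calls, and over 5% in 4 of 8 comparisons. Rates for dim genes or arrays that vary together were not tested. 32 gene lists with 765 members, of which 630 were measured, were written from general knowledge before the data were examined, as were the comparisons, thresholds and most tests and alternatives. They covered markers of macrophages, neutrophils, mast, T, B, endothelial, mesothelial, erythroid and fat cells, of muscle, pancreas, ovary and male tract, and pathways of metabolism, immunity, matrix, stress, clock and growth. With 1 probe set per gene, camera with a preset correlation of 0.01 tested each list, camera with an estimated correlation and fry were run beside it, and list p was adjusted within a comparison. Called members were also counted with p adjusted over the list alone.

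Genes were named by a rule: the 5 highest and 5 lowest called with arrays that do not overlap between groups and a higher group mean of at least 2 times the pseudocount; up to 4 called members per list; and 18 genes chosen in advance, with Y-linked and X-inactivation genes between the sexes. Correlations between comparisons were set beside 100 simulations of unchanged groups, which share arrays as the real ones do, and beside a split of shared arrays. Other groupings of the arrays were refitted, at most 100 per comparison. Alternatives were quantile normalization, a pseudocount of 1, the probe sets above the median of mean log2, no trend, the compared groups only, array weights, the batch as a fixed block, the replicate number as a block, and leaving out each array. Earlier or later arrays only, scan day as a random block, leaving out 4 doubted arrays and a covariate of the 52 probe sets that correlate with Slc39a1 within groups (r above 0.8) were added after the data were seen. Tables and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.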

Results

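Gene expression was measured in perigonadal adipose tissue of mice on 35 oligonucleotide arrays, 1 array per sample. The labels give an age of 22 weeks and do not state whether a sample came from 1 animal or from a pool. Lean mice (4 female and 4 male arrays) were compared with ob/ob mice, which lack functional leptin (4 female, 4 male), with Ay/+ mice, which carry the yellow allele of the agouti gene (4 female), and with males made obese by diet (3). Pioglitazone, an agonist of the nuclear receptor PPAR gamma, was given for 2 weeks at 10 mg/kg per day to Ay/+ females (3), ob/ob females (3) and diet-induced obese males (4). CL316243, an agonist of the beta3 adrenergic receptor, was given for 2 weeks at 3 mg/kg per day to ob/ob females (2). Few arrays limit the precision of every value. By experiment file form and scaling 22 arrays were earlier and 13 later. All ob/ob males were on later and all drug-treated females on earlier arrays. No scan day was shared in ob/ob against lean males, pioglitazone or CL316243 in ob/ob females, or CL316243 against pioglitazone. Effect and scan day are fully confounded there, and among untreated female groups on earlier arrays or without 4 doubted arrays. 4 arrays were doubted after the data were seen: Ay/+ female replicate 1 and ob/ob female replicate 4, whose correlation with their own groups was 0.872 and 0.877; pioglitazone-treated Ay/+ replicate 3, which has no dose in its label and a 5th percentile of signal of 23.9; and pioglitazone-treated diet-induced obese replicate 1, with a Gapdh 3' to 5' ratio of 46.9. Levels below are scaled signals as mean ± SD, fold changes are of signal plus 23, differences between groups are in log2, and a median is that of the log2 fold changes, or differences of effects, of a list. From or to a level below 23, the pseudocount, the size of a change is set by that floor. Counts over the list alone adjust p within it, and the Slc39a1 set is 52 probe sets that correlate with that gene within groups.

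The effect of leptin deficiency in females was read from ob/ob against lean females (n = 4 and 4). Macrophage and myeloid markers rose as a group: 28 of 34 members rose and 6 were not called (32 rose over the list alone), with median 1.86, adjusted p = 5.7e-32. Mmp12, the macrophage metalloelastase, rose from 71.4 ± 69.5 to 4609 ± 387 (log2 fold change 5.91, 60.3-fold higher, adjusted p = 4.8e-11). Cd68, a glycoprotein of macrophage lysosomes, rose from 269 ± 31.2 to 3265 ± 1538 (log2 fold change 3.30, adjusted p = 1.4e-10), with ob/ob replicate 4 at 1002 and the other ob/ob arrays at 3606 to 4322. Lysosomal genes rose with them: 26 of 38 members rose, 1 fell and 11 were not called (27 and 1 over the list alone), with median 0.85, adjusted p = 8.4e-15. Thermogenic genes fell: 1 of 13 members rose, 7 fell and 5 were not called (1 and 8 over the list alone), with median -1.13, adjusted p = 4.1e-04, or 0.104 with estimated correlation. Cidea, a lipid droplet protein of brown fat, fell from 2047 ± 739.6 to 39.2 ± 14.9 (log2 fold change -4.99, 31.8-fold lower, adjusted p = 6.5e-12), and Ucp1, the uncoupling protein of brown fat, fell from 856 ± 497 to 16.2 ± 15.4 (log2 fold change -4.25, adjusted p = 2.6e-07), to below the pseudocount. De novo lipogenesis genes fell: 11 of 18 members fell and 7 were not called (12 fell over the list alone), with median -1.003, adjusted p = 1.7e-05. Among these was Elovl6, a fatty acid elongase, which fell from 2701 ± 434 to 97.8 ± 20.4 (log2 fold change -4.50, adjusted p = 5.1e-10). In the oxidative phosphorylation list 43 of 64 members fell and 21 were not called (46 fell over the list alone), with median -0.93, adjusted p = 4.2e-17.

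In the same females immediate early genes rose: 11 of 20 members rose, 1 fell and 8 were not called (12 and 2 over the list alone), with median 0.93, adjusted p = 1.5e-05. Fos, a transcription factor subunit, rose from 165 ± 83.0 to 752 ± 105 (log2 fold change 2.12, adjusted p = 1.4e-06). The TCA cycle list fell (median -0.50, adjusted p = 0.00108, or 0.270 with estimated correlation). Extracellular matrix genes rose (median 0.33, adjusted p = 0.00140, or 0.104 with estimated correlation), as did cell cycle genes (median 0.42, adjusted p = 0.00158, or 0.228 with estimated correlation). Skeletal muscle markers fell (median -0.77, adjusted p = 1.0e-03, or 0.306 with estimated correlation). Their mean log2 signal was 7.05 to 8.17 on the lean arrays and 6.34 to 7.31 on the ob/ob arrays. Leptin mRNA, Lep, rose from 1133 ± 218 to 3371 ± 1671 (log2 fold change 1.46, adjusted p = 3.1e-04). Pparg, the receptor that pioglitazone binds, had a log2 fold change of 0.00, adjusted p = 0.993. limma called 3025 of 12422 probe sets, 1283 higher and 1742 lower. The median of all probe sets lay at -0.18 and moved to -0.05 with quantile normalization, a shift of 0.13, which called 1467 higher and 1332 lower. The count was 3236 with a batch block, 4328 on earlier arrays, 517 on later ones and 4869 without the doubted arrays. It moved to 5630 with array weights, 1406 with compared groups only and 1451 with a scan day block. Without ob/ob replicate 4 the 3' to 5' ratio, a sign of RNA quality, did not overlap, at 0.708 to 0.852 in ob/ob and 1.31 to 2.51 in lean females for Gapdh and 0.156 to 0.648 and 0.665 to 4.18 for Actb. On later arrays skeletal muscle (0.09) and cell cycle (-0.05) changed sign. Counts were 1912 or 1924 without ob/ob female replicate 1 or 2 and 2006 without lean female replicate 1.

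The Ay/+ females carry another cause of obesity, read against the same lean females (n = 4 and 4). The agouti gene itself rose from 79.5 ± 52.1 to 530.5 ± 161 (log2 fold change 2.56, adjusted p = 8.7e-06). Macrophage and myeloid markers rose: 17 of 34 members rose and 17 were not called (17 rose over the list alone), with median 0.71, adjusted p = 9.1e-12, or 0.246 with estimated correlation. Cd68 rose from 269 ± 31.2 to 941 ± 53.3 (log2 fold change 1.73, adjusted p = 5.3e-05). MHC class II genes rose: 7 of 13 members rose and 6 were not called (7 rose over the list alone), with median 0.94, adjusted p = 9.0e-07, or 0.164 with estimated correlation. H2-DMb1, which helps to load peptides onto class II molecules, rose from 207 ± 39.6 to 1229 ± 358 (log2 fold change 2.41, adjusted p = 4.5e-06). De novo lipogenesis genes fell: 7 of 18 members fell and 11 were not called (9 fell over the list alone), with median -0.54, adjusted p = 0.00328, or 0.256 with estimated correlation. Elovl6 fell from 2701 ± 434 to 127 ± 28.6 (log2 fold change -4.19, 18.3-fold lower, adjusted p = 6.5e-09), and Me1, the cytosolic malic enzyme, fell from 7265 ± 1627 to 1535 ± 524 (log2 fold change -2.25, adjusted p = 2.1e-08). Oxidative phosphorylation genes fell (29 of 64 members fell and 35 were not called, 32 fell over the list alone, with median -0.47, adjusted p = 1.2e-05, or 0.256 with estimated correlation), as did TCA cycle genes (median -0.48, adjusted p = 6.5e-04, or 0.289 with estimated correlation). Cidea fell from 2047 ± 739.6 to 170.3 ± 78.8 (log2 fold change -3.42, adjusted p = 3.6e-08).

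Leptin mRNA, Lep, rose in Ay/+ females from 1133 ± 218 to 4486 ± 346 (log2 fold change 1.98, adjusted p = 1.0e-05). Serpina3n, a secreted protease inhibitor, rose from 646 ± 144 to 4736 ± 886 (log2 fold change 2.83, adjusted p = 1.5e-11), and Saa3, an acute phase protein, rose from 349 ± 207 to 2169 ± 721 (log2 fold change 2.67, adjusted p = 1.0e-05). B cell and plasma cell markers rose (median 0.20, adjusted p = 0.0122, or 0.256 with estimated correlation). The adipocyte marker list also passed its test (median 0.11, adjusted p = 0.00421, or 0.293 with estimated correlation; -0.03 and 0.109 with quantile normalization), with 5 members higher and 1 lower, 5 and 1 adjusted over the list alone. The thermogenic list fell (median -0.82, adjusted p = 0.0122, or 0.293 with estimated correlation), but its adjusted p was 0.131 without Ay/+ replicate 1. The pancreas list, of acinar and islet genes, rose (median 0.36, adjusted p = 0.0122, or 0.310 with estimated correlation), with an adjusted p of 0.0699 without Ay/+ replicate 4. limma called 2207 probe sets, 777 higher and 1430 lower, against 1086 and 1294 with quantile normalization. The count was 2421 with a batch block, 3573 on earlier arrays, 162 on later ones and 4102 without the doubted arrays. Others gave 440 with compared groups only, 1328 with a scan day block and 1268 with the Slc39a1 set as a covariate. The Gapdh 3' to 5' ratio did not overlap, at 0.741 to 1.02 in Ay/+ and 1.31 to 2.51 in lean females. On later arrays adipocyte (-0.21), neutrophil (-0.60) and pancreas lists (-0.38) changed sign. Counts were 1459 without lean female replicate 1 and 3383 without Ay/+ replicate 1.

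Whether the obesity models of the females differ was tested by ob/ob against Ay/+ females (n = 4 and 4). Macrophage and myeloid markers were higher in ob/ob: 23 of 34 members were higher and 11 were not called (27 were higher over the list alone), with median 1.10, adjusted p = 5.8e-12, or 0.139 with estimated correlation. Adam8, a metalloprotease of leukocytes, was 113 ± 175 in Ay/+ and 2263 ± 1213 in ob/ob (4.58, adjusted p = 2.2e-07). Il1rn, the interleukin-1 receptor antagonist, was 57.3 ± 49.4 and 618 ± 218 (3.17, adjusted p = 4.1e-07). Lysosomal genes followed: 23 of 38 members were higher, 2 were lower and 13 were not called (26 and 4 over the list alone), with median 0.86, adjusted p = 5.3e-08, or 0.121 with estimated correlation. MHC class II genes were lower in ob/ob: 6 of 13 members were lower and 7 were not called (7 were lower over the list alone), with median -0.88, adjusted p = 5.2e-05, or 0.139 with estimated correlation. H2-Eb1, a class II chain, was 5444 ± 867 in Ay/+ and 1402 ± 749 in ob/ob (-2.14, adjusted p = 3.7e-05). Immediate early genes were higher in ob/ob (median 0.74, adjusted p = 7.0e-05, or 0.0740 with estimated correlation), as were unfolded protein response genes (median 0.55, adjusted p = 0.00785, or 0.190 with estimated correlation). T and NK cell markers (median -0.48, adjusted p = 0.00837, or 0.465 with estimated correlation) and oxidative phosphorylation genes (median -0.43, adjusted p = 1.9e-06, or 0.190 with estimated correlation) were lower. The ovary and uterus list was lower (median -0.45, adjusted p = 0.0469, or 0.483 with estimated correlation), with an adjusted p of 0.0608 to 0.112 without any 1 of 4 arrays. The agouti gene was 530.5 ± 161 in Ay/+ and 15.4 ± 2.85 in ob/ob. limma called 2686 probe sets, 1451 higher and 1235 lower in ob/ob. The count was 2956 with a batch block, 4745 on earlier arrays, 244 on later ones and 5357 without the doubted arrays. Other fits gave 5352 with array weights, 225 with compared groups only, 1309 with a scan day block and 311 with the Slc39a1 set as a covariate. Without the doubted arrays the Actb 3' to 5' ratio was 0.156 to 0.648 in ob/ob and 0.866 to 1.11 in Ay/+. Later arrays hold 1 array of each group here, both doubted. On them Cd68 (-0.02 against 1.57 on all arrays), T and NK (0.25), ovary and uterus (0.15) and pancreas (0.14) changed sign. The unfolded protein response list stood there at a median of 0.0649 with its test turned downward. Counts were 1494, 1532 or 4332 without Ay/+ replicate 2, 4 or 1 and 1711 without ob/ob female replicate 2.

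Leptin deficiency in males was read from ob/ob against lean males (n = 4 and 4). Markers of macrophages and myeloid cells rose: 29 of 34 members rose and 5 were not called (31 rose over the list alone), with median 1.92, adjusted p = 2.1e-36. Mmp12 rose from 198 ± 108 to 6592 ± 1097 (log2 fold change 5.01, adjusted p = 1.5e-09) and Cd68 from 582 ± 74.0 to 5434 ± 896 (log2 fold change 3.17, adjusted p = 3.4e-10). Lysosomal genes rose: 16 of 38 members rose, 1 fell and 21 were not called (20 and 1 over the list alone), with median 0.62, adjusted p = 7.8e-10. Ctsk, the protease cathepsin K, rose from 155 ± 18.4 to 2303 ± 561 (log2 fold change 3.68, 12.8-fold higher, adjusted p = 1.1e-09). Cell cycle genes rose: 12 of 26 members rose and 14 were not called (18 rose over the list alone), with median 0.98, adjusted p = 2.4e-12. Cdk1, the mitotic kinase, rose from 17.97 ± 7.54 to 260.3 ± 59.6 (log2 fold change 2.78, adjusted p = 5.2e-09). Cytokine and chemokine genes rose (median 0.29, adjusted p = 2.4e-04), as did immediate early genes (median 0.31, adjusted p = 0.00188, or 0.0533 with estimated correlation).

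Adipocyte markers fell in the ob/ob males: 11 of 22 members fell and 11 were not called (12 fell over the list alone), with median -0.81, adjusted p = 5.3e-09. Slc2a4, the insulin-responsive glucose transporter, fell from 861 ± 148 to 128 ± 8.92 (log2 fold change -2.54, adjusted p = 1.1e-08), and Rbp4, the retinol carrier, fell from 4157 ± 24.0 to 629 ± 86.1 (log2 fold change -2.69, adjusted p = 4.9e-12). De novo lipogenesis genes fell: 9 of 18 members fell and 9 were not called (9 fell over the list alone), with median -0.85, adjusted p = 4.0e-08. Fasn, fatty acid synthase, fell from 5066 ± 1019 to 1386 ± 297 (log2 fold change -1.86, adjusted p = 1.0e-07). Endothelial markers fell: 10 of 13 members fell and 3 were not called (11 fell over the list alone), with median -0.92, adjusted p = 5.6e-08. Kdr, a receptor for vascular endothelial growth factor, fell from 527 ± 73.3 to 171 ± 34.0 (log2 fold change -1.51, adjusted p = 3.7e-04). TCA cycle genes fell (median -0.63, adjusted p = 5.3e-09), as did oxidative phosphorylation (median -0.43, adjusted p = 7.1e-08, or 0.0764 with estimated correlation), fatty acid oxidation (median -0.37, adjusted p = 1.5e-04, or 0.127 with estimated correlation) and PPAR target genes (median -0.35, adjusted p = 9.9e-04, or 0.127 with estimated correlation). Lep had a log2 fold change of 0.52, adjusted p = 0.332, and Ucp1 of -0.08, adjusted p = 0.972, at 9.51 ± 5.03 and 7.51 ± 1.44, both below the pseudocount. ob/ob male replicate 1 stood apart in markers of the male reproductive tract, at a mean log2 signal of 7.77 against 5.53 to 5.67. limma called 1314 probe sets, 698 higher and 616 lower, 1442 with a batch block and 1383 on later arrays. Others gave 2554 with array weights and 2005 with compared groups only. The earlier arrays hold no ob/ob males, so no earlier value could be had.

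The effect of the diet was read from diet-induced obese against lean males (n = 3 and 4). Markers of macrophages and myeloid cells rose: 19 of 34 members rose and 15 were not called (27 rose over the list alone), with median 1.22, adjusted p = 3.1e-37. Cd68 rose from 582 ± 74.0 to 3318 ± 629 (log2 fold change 2.46, adjusted p = 2.1e-06) and Mmp12 from 198 ± 108 to 4051 ± 1047 (log2 fold change 4.30, adjusted p = 2.0e-06). Cytokine and chemokine genes rose: 8 of 38 members rose and 30 were not called (9 rose over the list alone), with median 0.20, adjusted p = 8.6e-08. Ccl2, a monocyte chemoattractant, rose from 456 ± 163 to 3473 ± 914 (log2 fold change 2.90, adjusted p = 5.5e-07), and Saa3 from 525 ± 349.7 to 3292 ± 378 (log2 fold change 2.79, adjusted p = 5.1e-05). Cell cycle genes rose: 5 of 26 members rose and 21 were not called (8 rose over the list alone), with median 0.45, adjusted p = 1.8e-10. De novo lipogenesis genes fell: 4 of 18 members fell and 14 were not called (7 fell over the list alone), with median -0.50, adjusted p = 1.2e-05. Mid1ip1, which activates acetyl-CoA carboxylase, fell from 2262 ± 555 to 557 ± 157 (log2 fold change -1.98, adjusted p = 1.2e-04). Slc2a4 fell from 861 ± 148 to 232 ± 23.4 (log2 fold change -1.78, adjusted p = 1.5e-04). The endothelial list (median -0.61, adjusted p = 1.1e-05) and the TCA cycle list (median -0.46, adjusted p = 5.8e-08) also fell. The lysosome list (median 0.30, adjusted p = 1.2e-06, or 0.0766 with estimated correlation) and MHC class II list (median 0.39, adjusted p = 0.00118, or 0.138 with estimated correlation) rose. Lipid efflux genes rose (median 0.51, adjusted p = 0.0263, or 0.107 with estimated correlation), with an adjusted p of 0.0716 without diet-induced obese replicate 1. limma called 230 probe sets, 152 higher and 78 lower. The count was 248 with a batch block, 210 on earlier arrays, 69 on later ones and 497 without the doubted arrays. Other fits gave 631 with array weights. Counts were 117 without diet-induced obese replicate 2 and 152 or 153 without lean male replicate 4 or 1.

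Whether genetic and dietary obesity differ in males was tested by ob/ob against diet-induced obese males (n = 4 and 3). Adipocyte markers were lower in ob/ob: 3 of 22 members were lower and 19 were not called (10 were lower over the list alone), with median -0.72, adjusted p = 6.0e-13. Rbp4 was 4116 ± 1078 in diet-induced obesity and 629 ± 86.1 in ob/ob (-2.64, adjusted p = 4.3e-10). Cyp2e1, a cytochrome P450, was 6021 ± 1961 and 327 ± 78.0 (-4.09, adjusted p = 9.5e-04). Fasn was 3995 ± 570.2 and 1386 ± 297 (-1.53, adjusted p = 2.4e-04). Macrophage and myeloid markers were higher in ob/ob: 2 of 34 members were higher and 32 were not called (13 were higher over the list alone), with median 0.67, adjusted p = 1.1e-09, or 0.131 with estimated correlation. Clec4d, a myeloid lectin receptor, was 124 ± 22.4 and 848 ± 240.1 (2.53, adjusted p = 0.00507). Mast cell markers were higher (median 0.66, adjusted p = 0.00249, or 0.0615 with estimated correlation) and erythroid genes lower (median -0.69, adjusted p = 3.3e-04, or 0.0615 with estimated correlation). limma called 109 probe sets, 32 higher and 77 lower in ob/ob, 87 with a batch block, 17 on later arrays and 457 without the doubted arrays. Others gave 599 with array weights, 185 with compared groups only and 196 above the median of mean log2. It was 39 to 61 without any 1 of 5 arrays.

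Lean males and lean females (n = 4 and 4) were compared. Mesothelial and epithelial markers averaged 8.07 and 8.06 log2 on lean female replicates 1 and 3, but 6.88 and 6.64 on 2 and 4. The part of this in comparisons with lean females was not tested. Thermogenic genes were lower in males: 7 of 13 members were lower and 6 were not called (8 were lower over the list alone), with median -1.09, adjusted p = 7.8e-05, or 0.266 with estimated correlation. Ucp1 was 856 ± 497 in females and 9.51 ± 5.03 in males (-4.46, adjusted p = 3.6e-07, the males below the pseudocount), and Cidea 2047 ± 739.6 and 203.3 ± 44.2 (-3.12, adjusted p = 3.2e-07). Macrophage and myeloid markers were higher in males: 14 of 34 members were higher and 20 were not called (15 were higher over the list alone), with median 0.62, adjusted p = 1.1e-08, or 0.276 with estimated correlation. Lep was 1133 ± 218 in females and 3437 ± 684 in males (1.58, adjusted p = 4.0e-04). Hsd11b1, which regenerates active glucocorticoid, was 318 ± 103 and 2027 ± 336 (2.63, adjusted p = 2.0e-08). Skeletal muscle markers were lower in males (13 of 24 members were lower and 11 were not called, 16 were lower over the list alone, with median -1.20, adjusted p = 1.5e-07, or 0.266 with estimated correlation), and the lean female arrays held 7.05 to 8.17 of that list's mean log2 signal against 6.32 to 6.39. Lysosome (median 0.41, adjusted p = 1.3e-05, or 0.266 with estimated correlation), endothelial (median 0.37, adjusted p = 0.00571, or 0.393 with estimated correlation) and adipocyte lists (median 0.06, adjusted p = 0.00568, or 0.396 with estimated correlation) were higher and oxidative phosphorylation lower (median -0.43, adjusted p = 7.8e-05, or 0.393 with estimated correlation). Xist, the transcript of X inactivation, was 624 ± 126 in females and 16.6 ± 12.7 in males. The Y-linked Eif2s3y was 23.0 ± 9.33 and 127 ± 33.7, and Kdm5d was not called (-0.93, adjusted p = 0.115). limma called 1948 probe sets, 648 higher and 1300 lower in males, and 789 and 633 with quantile normalization, which moved the median of all probe sets from -0.20 to -0.01, a shift of 0.19. The count was 1867 with a batch block, 1802 on earlier arrays, 395 on later ones and 3345 without the doubted arrays. It moved to 3593 with array weights, 1039 with a scan day block and 1251 above the median of mean log2. On later arrays the adipocyte list (-0.04) changed sign. Counts were 726 or 924 without lean female replicate 1 or 3 and 1079, 1255 or 1296 without lean male replicate 4, 1 or 2.

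Whether leptin deficiency acts alike in the sexes was tested as the ob/ob effect in males minus that in females. The thermogenic list differed: 4 of 13 members had a higher effect in males and 9 were not called (6 had a higher effect in males over the list alone), with median 0.82, adjusted p = 0.00400, or 0.334 with estimated correlation. Cidea was 2047 ± 739.6 in lean females, 39.2 ± 14.9 in ob/ob females, 203.3 ± 44.2 in lean males and 34.3 ± 7.80 in ob/ob males (difference 3.02, adjusted p = 3.4e-04). Ucp1 was 856 ± 497 in lean females, 16.2 ± 15.4 in ob/ob females, 9.51 ± 5.03 in lean males and 7.51 ± 1.44 in ob/ob males (difference 4.17, adjusted p = 5.7e-04). Its signal lay below the pseudocount in both groups of males, where a fall could not be measured, so its difference holds the female fall alone and leaves open whether the sexes differ. Cidea ended near that floor in both sexes. Skeletal muscle markers also had a higher effect in males (median 0.86, adjusted p = 0.00374, or 0.580 with estimated correlation), with mean log2 signals of 7.05 to 8.17 in lean and 6.34 to 7.31 in ob/ob females against 6.32 to 6.39 and 6.37 to 6.51 in males. Adipocyte markers had the lower effect in males: 8 of 22 members were lower and 14 were not called (9 were lower over the list alone), with median -0.87, adjusted p = 1.3e-07, or 0.140 with estimated correlation. Slc2a4 was 491 ± 163 in lean females, 355 ± 136 in ob/ob females, 861 ± 148 in lean males and 128 ± 8.92 in ob/ob males (difference -2.06, adjusted p = 8.5e-04). Hsd11b1 was 318 ± 103 in lean females, 839 ± 353 in ob/ob females, 2027 ± 336 in lean males and 397 ± 52.5 in ob/ob males (difference -3.55, adjusted p = 1.6e-07). Oxidative phosphorylation (median 0.52, adjusted p = 6.5e-05, or 0.334 with estimated correlation) and cell cycle lists (median 0.62, adjusted p = 0.00400, or 0.334 with estimated correlation) had the higher effect in males, and endothelial markers the lower (median -0.50, adjusted p = 0.00374, or 0.334 with estimated correlation). limma called 706 probe sets, 353 in each direction, and 262 higher and 399 lower with quantile normalization, which moved the median of all probe sets from 0.23 to 0.03, a shift of -0.19. The count was 967 with a batch block, 226 on later arrays and 2642 without the doubted arrays. Others gave 3988 with array weights, 237 with a scan day block and 1497 with the Slc39a1 set as a covariate. On later arrays the adipocyte list was at -0.19 and lysosome (0.25), fatty acid oxidation (0.28) and skeletal muscle lists (-0.25) changed sign. Leaving out 1 array, limma called 418 to 455 without any 1 of 5 arrays, 1076 without lean female replicate 4 and 1671 without ob/ob female replicate 4.

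**Figure D1:**
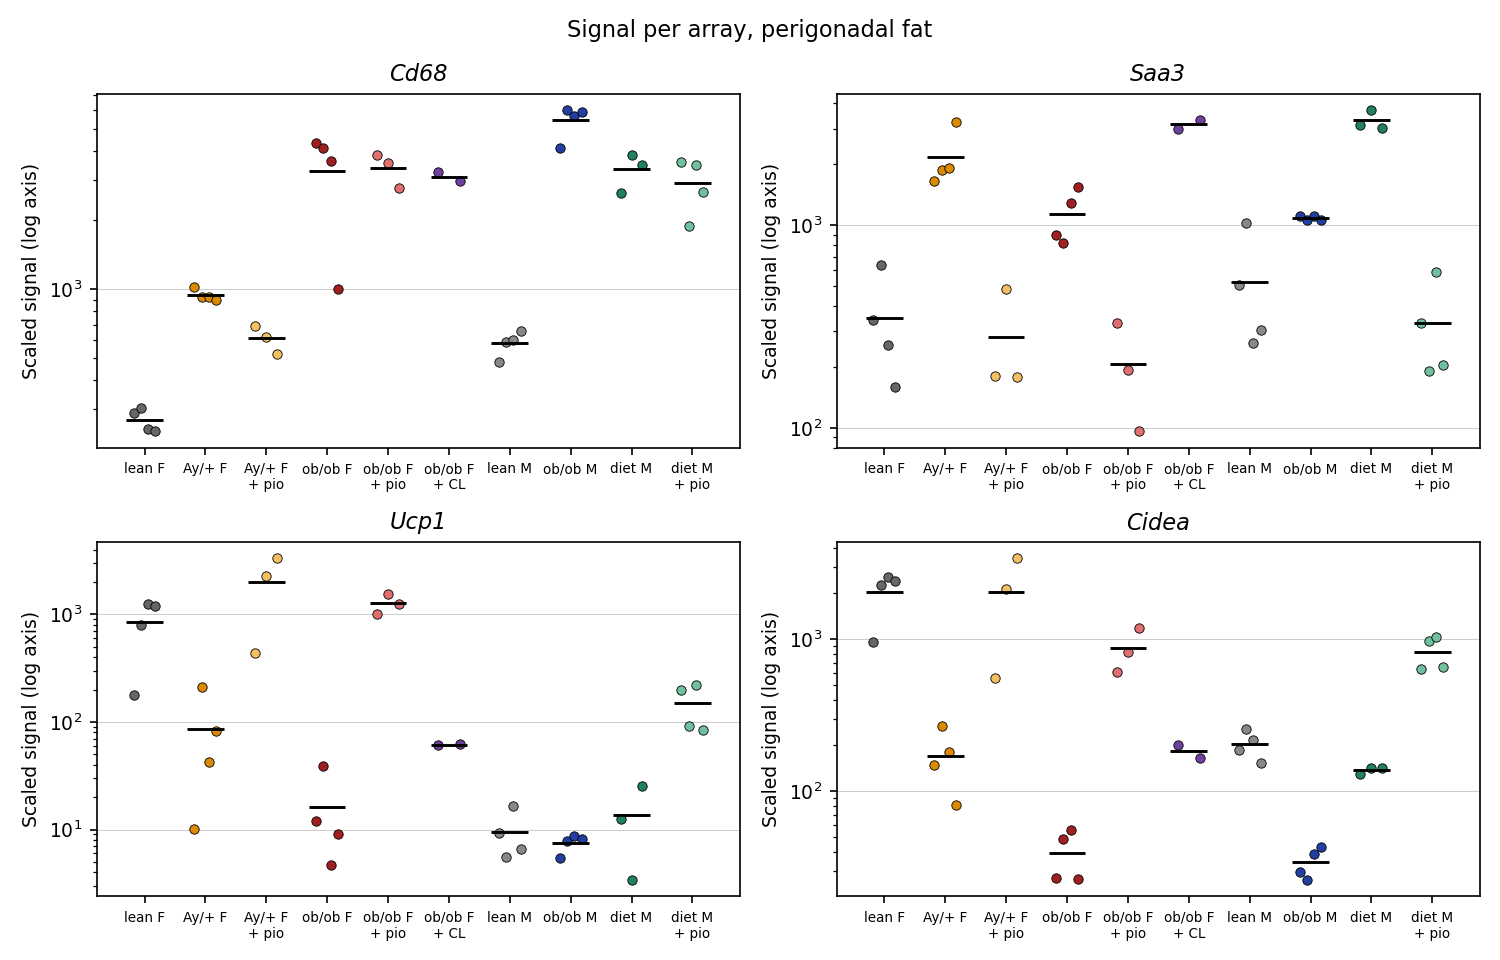
Scaled signal on a log axis of Cd68, Saa3, Ucp1 and Cidea on each of the 35 arrays in 10 groups, with points for arrays and bars for group means. Ucp1 averaged 856 in lean females and 16.2 in ob/ob females, and 1268 in ob/ob females given pioglitazone.

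Pioglitazone in Ay/+ females was read from treated against untreated mice (n = 3 and 4). Thermogenic genes rose: 5 of 13 members rose and 8 were not called (8 rose over the list alone), with median 1.02, adjusted p = 5.3e-08. Ucp1 rose from 86.5 ± 88.2 to 2010.2 ± 1464 (log2 fold change 4.15, 17.8-fold higher, adjusted p = 9.6e-06) and Cidea from 170.3 ± 78.8 to 2033 ± 1428 (log2 fold change 3.17, adjusted p = 2.2e-06). Fatty acid oxidation genes rose: 12 of 22 members rose and 10 were not called (17 rose over the list alone), with median 0.89, adjusted p = 3.7e-16. Slc25a20, the mitochondrial carnitine carrier, rose from 591 ± 89.6 to 1851 ± 143 (log2 fold change 1.62, adjusted p = 5.8e-05). TCA cycle genes rose: 12 of 21 members rose and 9 were not called (18 rose over the list alone), with median 0.85, adjusted p = 3.1e-17. In the oxidative phosphorylation list 24 of 64 members rose and 40 were not called (37 rose over the list alone), with median 0.75, adjusted p = 4.2e-21. PPAR target genes rose: 9 of 25 members rose and 16 were not called (11 rose over the list alone), with median 0.51, adjusted p = 4.7e-09. Aqp7, the glycerol channel of adipocytes, rose from 359 ± 97.9 to 1341 ± 235 (log2 fold change 1.86, adjusted p = 4.1e-05). Saa3 fell from 2169 ± 721 to 281 ± 177 (log2 fold change -2.94, adjusted p = 1.8e-05), and Lbp, the lipopolysaccharide-binding protein, fell from 2466 ± 208 to 452 ± 36.5 (log2 fold change -2.39, adjusted p = 2.2e-10). Extracellular matrix genes fell (3 of 40 members fell and 37 were not called, 5 fell over the list alone, with median -0.24, adjusted p = 3.8e-06). Macrophage markers fell (2 of 34 members fell and 32 were not called, 8 fell over the list alone, with median -0.50, adjusted p = 3.6e-08, or 0.155 with estimated correlation), while Cd68 had a log2 fold change of -0.61, adjusted p = 0.326. Cholesterol synthesis genes rose (median 0.70, adjusted p = 4.4e-05, or 0.0563 with estimated correlation) and MHC class II genes fell (median -0.64, adjusted p = 0.00188, or 0.180 with estimated correlation). limma called 377 probe sets, 264 higher and 113 lower, 448 with a batch block, 1221 on earlier arrays and 1095 without the doubted arrays. Other fits gave 641 with array weights and 90 with compared groups only. The count was 224 without treated Ay/+ replicate 3 and 880 without Ay/+ replicate 1.

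In ob/ob females pioglitazone was read from treated against untreated mice (n = 3 and 4). Thermogenic genes rose: 5 of 13 members rose and 8 were not called (7 rose over the list alone), with median 0.98, adjusted p = 1.2e-15. Ucp1 rose from 16.2 ± 15.4 to 1268 ± 271 (log2 fold change 5.09, adjusted p = 5.1e-07), from below the pseudocount, and Cidea from 39.2 ± 14.9 to 871 ± 289 (log2 fold change 3.82, adjusted p = 2.1e-07). TCA cycle genes rose: 7 of 21 members rose and 14 were not called (17 rose over the list alone), with median 0.78, adjusted p = 2.3e-25. Suclg1, a subunit of succinyl-CoA ligase, rose from 650.2 ± 121 to 1454 ± 87.5 (log2 fold change 1.15, adjusted p = 9.2e-04). Fatty acid oxidation genes rose (8 of 22 members rose and 14 were not called, 15 rose over the list alone, with median 0.78, adjusted p = 1.6e-20), as did oxidative phosphorylation genes (11 of 64 members rose and 53 were not called, 20 rose over the list alone, with median 0.41, adjusted p = 1.5e-19). PPAR target genes rose: 9 of 25 members rose and 16 were not called (10 rose over the list alone), with median 0.50, adjusted p = 1.5e-19. Fabp3, a fatty acid binding protein, rose from 30.5 ± 11.2 to 336 ± 35.1 (log2 fold change 2.76, adjusted p = 4.0e-05). Lcn2, a secreted lipocalin of neutrophils, fell from 595 ± 279 to 28.1 ± 7.09 (log2 fold change -3.45, adjusted p = 7.0e-04), and Saa3 fell from 1139 ± 346 to 206 ± 117 (log2 fold change -2.43, adjusted p = 7.0e-04). MHC class II genes fell (2 of 13 members fell and 11 were not called, 4 fell over the list alone, with median -0.28, adjusted p = 6.5e-05, or 0.0944 with estimated correlation), and H2-Aa, a class II chain, fell from 2217 ± 1090.3 to 562 ± 101.5 (log2 fold change -1.78, adjusted p = 8.0e-04). Neutrophil markers fell (median -0.22, adjusted p = 0.00121, or 0.156 with estimated correlation). The adipocyte list passed its test upward with a median of -0.01 and a mean of 0.23 (adjusted p = 0.0285, adjusted p = 0.388 with an estimated correlation), with an adjusted p of 0.0786 without treated ob/ob replicate 2 and 0.0901 without treated ob/ob replicate 3. Cd68 had a log2 fold change of 0.24, adjusted p = 0.999. limma called 132 probe sets, 91 higher and 41 lower, 147 with a batch block and 131 on earlier arrays. Other fits gave 699 with array weights, 14 with compared groups only and 56 with a scan day block. Counts were 44, 56 or 87 without treated ob/ob replicate 3, 2 or 1.

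In diet-induced obese males pioglitazone was read from treated against untreated mice (n = 4 and 3). Fatty acid oxidation genes rose: 11 of 22 members rose and 11 were not called (15 rose over the list alone), with median 0.86, adjusted p = 3.7e-20. Ehhadh, a peroxisomal enzyme of that pathway, rose from 29.97 ± 9.93 to 199 ± 66.1 (log2 fold change 2.04, adjusted p = 1.6e-05). PPAR target genes rose: 8 of 25 members rose and 17 were not called (12 rose over the list alone), with median 0.59, adjusted p = 4.4e-16. Pdk4, the kinase that inactivates pyruvate dehydrogenase, rose from 264 ± 149 to 3277 ± 995 (log2 fold change 3.602, 12.1-fold higher, adjusted p = 2.7e-07). TCA cycle (7 of 21 members rose and 14 were not called, 16 rose over the list alone, with median 0.75, adjusted p = 6.7e-21) and oxidative phosphorylation genes rose (11 of 64 members rose and 53 were not called, 40 rose over the list alone, with median 0.61, adjusted p = 1.0e-24). Thermogenic genes rose (5 of 13 members rose and 8 were not called, 6 rose over the list alone, with median 0.41, adjusted p = 3.4e-07), and Cidea rose from 138 ± 6.55 to 821 ± 207 (log2 fold change 2.36, adjusted p = 3.3e-04). MHC class II genes fell: 5 of 13 members fell and 8 were not called (5 fell over the list alone), with median -0.63, adjusted p = 1.8e-07. Cytokine and chemokine genes fell (4 of 38 members fell and 34 were not called, 4 fell over the list alone, with median -0.27, adjusted p = 1.8e-04), and Ccl2 fell from 3473 ± 914 to 852 ± 99.5 (log2 fold change -1.97, adjusted p = 3.2e-04). Saa3 fell from 3292 ± 378 to 328 ± 183 (log2 fold change -3.37, adjusted p = 2.3e-06), and Serpina3n from 3138 ± 488 to 382 ± 17.3 (log2 fold change -2.95, adjusted p = 4.2e-11). Macrophage markers passed their test downward (median -0.28, adjusted p = 0.00436, or 0.642 with estimated correlation), with an adjusted p of 0.153 without diet-induced obese replicate 2, 0.0549 without diet-induced obese replicate 3 and 0.272 without treated diet-induced obese replicate 2. limma called 176 probe sets, 94 higher and 82 lower, 162 with a batch block, 59 on earlier arrays, 69 on later ones and 352 without the doubted arrays. It moved to 570 with array weights and 73 with compared groups only. The Actb 3' to 5' ratio was 0.869 to 3.27 in treated and 0.734 to 0.825 in untreated mice. The count was 111 without diet-induced obese replicate 2.

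Whether pioglitazone acts alike in the female models was tested as its effect in ob/ob minus that in Ay/+. Fst, follistatin, an inhibitor of activin, was 53.1 ± 21.9 and 88.6 ± 19.4 in untreated and treated Ay/+ females and 120.3 ± 29.8 and 29.1 ± 23.7 in untreated and treated ob/ob females (difference -2.14, adjusted p = 0.0345). For Fst the adjusted p was 0.0619 to 0.388 without any 1 of 10 arrays. Nrep was 457 ± 79.9 and 117 ± 58.8 in untreated and treated Ay/+ females and 252 ± 36.6 and 264 ± 61.7 in untreated and treated ob/ob females (difference 1.89, adjusted p = 0.0161). For Nrep the adjusted p was 0.0598 to 0.0970 without any 1 of 4 arrays. Emp1, a membrane protein of epithelia, was 1902 ± 1057 and 342 ± 37.3 in untreated and treated Ay/+ females and 2399 ± 779 and 1892 ± 141 in untreated and treated ob/ob females (difference 1.98, adjusted p = 0.0161). For Emp1 the adjusted p was 0.0588 to 0.0970 without any 1 of 6 arrays. Ucp1 differed by 0.94, adjusted p = 0.987, and Cidea by 0.65, adjusted p = 0.987. Macrophage markers (median 0.34, adjusted p = 1.6e-04, or 0.934 with estimated correlation) and oxidative phosphorylation genes (median -0.25, adjusted p = 0.0278, or 0.934 with estimated correlation) passed the list test with the preset correlation. The adjusted p was 0.0600 to 0.332 without any 1 of 4 arrays for the macrophage list. Its median was 0.11 on earlier arrays, 0.01 with array weights and -0.00140 without the doubted arrays. With quantile normalization the adjusted p of oxidative phosphorylation was 0.398. It was 0.0525 to 0.788 without any 1 of 6 arrays. limma called 3 probe sets, 2 higher and 1 lower, of 626 at an unadjusted p under 0.05. The count was 3 with a batch block, 46 on earlier arrays and 30 without the doubted arrays. It moved to 55 with array weights and 1 with compared groups only. With 1 array left out it was 0 to 1 without any 1 of 6 arrays and 9 without Ay/+ replicate 1.

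**Figure D2:**
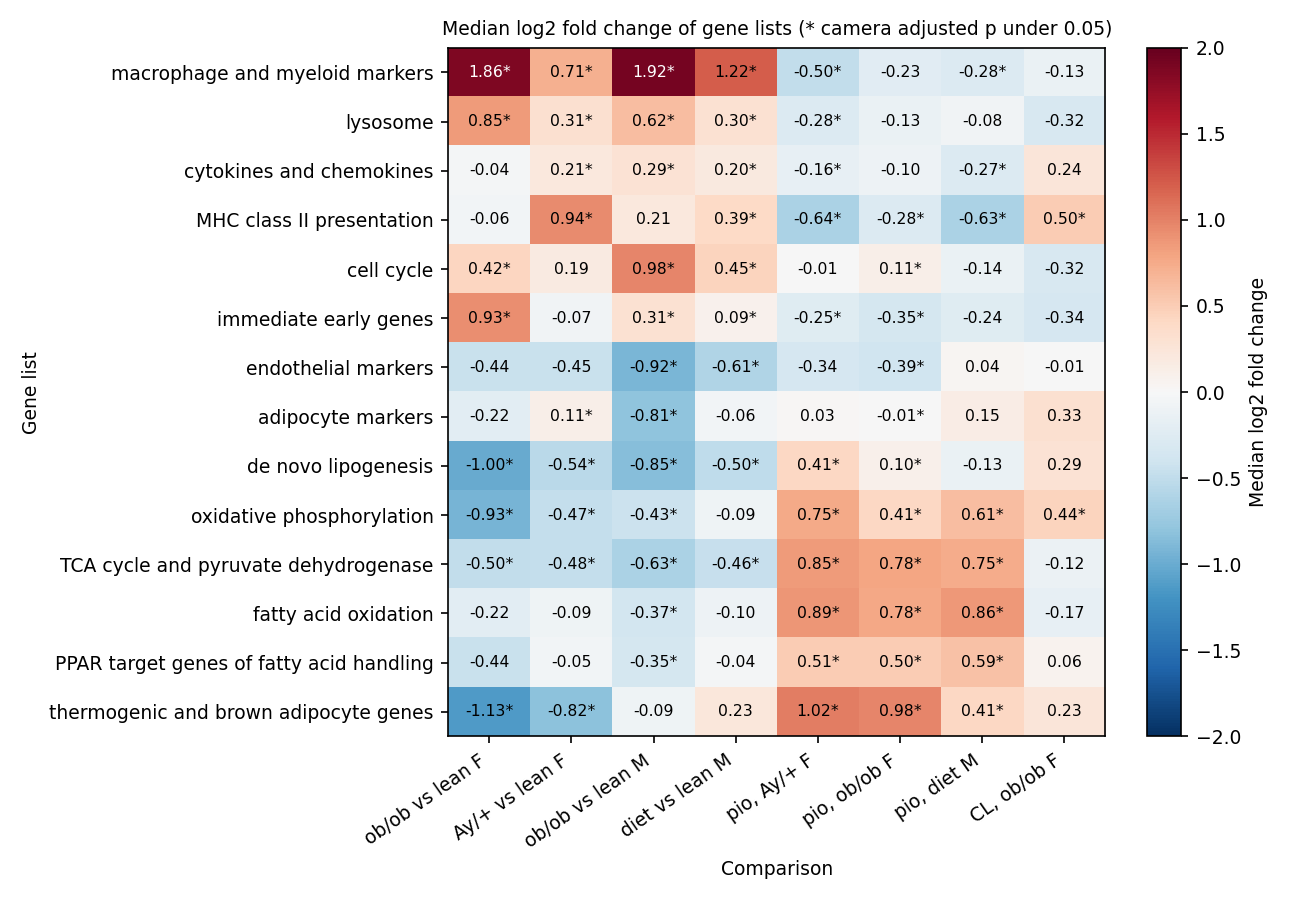
Median log2 fold change, as colour and number, of 14 gene lists in 8 comparisons, with an asterisk where the camera adjusted p is under 0.05. Macrophage markers had medians of 1.86, 0.71, 1.92 and 1.22 in the obesity comparisons, and fatty acid oxidation genes of 0.89, 0.78 and 0.86 with pioglitazone.

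CL316243 in ob/ob females was read from 2 treated against 4 untreated arrays. Oxidative phosphorylation genes rose: 7 of 64 members rose and 57 were not called (12 rose over the list alone), with median 0.44, adjusted p = 4.0e-09, or 0.351 with estimated correlation. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, rose from 248 ± 31.2 to 1074 ± 194 (log2 fold change 2.02, adjusted p = 0.00256), with an adjusted p of 0.109 without CL316243 replicate 1. Cpe, carboxypeptidase E, fell from 653 ± 58.8 to 91.6 ± 10.6 (log2 fold change -2.56, 5.89-fold lower, adjusted p = 3.8e-04). Plin2, a lipid droplet coat protein, rose from 2114 ± 2000.4 to 12619 ± 152 (log2 fold change 2.95, adjusted p = 0.00485), with an adjusted p of 0.109 without CL316243 replicate 1 and 0.0830 without CL316243 replicate 2. Slc39a1, a zinc transporter, rose from 576 ± 609 to 10293 ± 1869 (log2 fold change 4.54, adjusted p = 0.00406), with an adjusted p of 0.109 without CL316243 replicate 1 and 0.0641 without CL316243 replicate 2. Sdc4, a cell surface proteoglycan, rose from 189 ± 201 to 2354 ± 54.1 (log2 fold change 3.87, adjusted p = 0.00208), with an adjusted p of 0.0915 without CL316243 replicate 1 and 0.0528 without CL316243 replicate 2. Both belong to the Slc39a1 set, and Slc39a1 was also at 5131 to 5543 on 3 of the 4 untreated Ay/+ female arrays. Ucp1 had a log2 fold change of 1.18, adjusted p = 0.321, at 16.2 ± 15.4 and 61.3 ± 1.12. The MHC class II list passed its test upward (median 0.50, adjusted p = 0.0324, or 0.530 with estimated correlation), with an adjusted p of 0.0823 without CL316243 replicate 2, 0.0592 without ob/ob female replicate 2 and 0.142 without ob/ob female replicate 4. limma called 464 probe sets, 193 higher and 271 lower, and 171 and 143 with quantile normalization. The count was 470 with a batch block, 1714 on earlier arrays, 1982 without the doubted arrays and 6 with that set as a covariate. The set mean was 10.65 and 10.72 treated and 8.47 to 9.63 untreated, so the 6 cannot tell set from drug. It moved to 3186 with array weights, 20 with compared groups only and 32 with a scan day block. Without ob/ob replicate 4 the 3' to 5' ratio was 1.52 to 1.53 in treated and 0.156 to 0.648 in untreated mice for Actb and 0.998 to 1.11 and 0.708 to 0.852 for Gapdh. The count was 4 without CL316243 replicate 1, 14 without CL316243 replicate 2, 146 without ob/ob female replicate 2, 165 without ob/ob female replicate 1, 209 without ob/ob female replicate 3 and 1261 without ob/ob female replicate 4, and without a treated array the other is assumed to vary like the other groups.

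**Figure D3:**
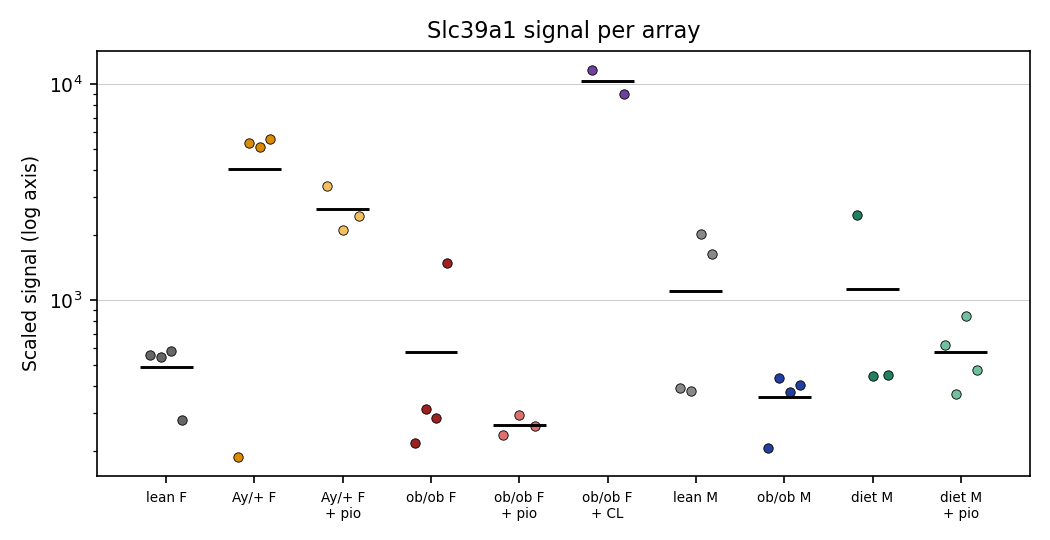
Scaled signal of Slc39a1 on a log axis for each of the 35 arrays in 10 groups, with points for arrays and bars for group means. The CL316243 arrays lie at 11615 and 8972, and Ay/+ female replicate 1 at 188 against 5131 to 5543 on the other Ay/+ females.

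Whether the drugs differ in ob/ob females was tested by CL316243 against pioglitazone (n = 2 and 3). TCA cycle genes were lower with CL316243: 12 of 21 members were lower and 9 were not called (13 were lower over the list alone), with median -0.91, adjusted p = 4.8e-10, or 0.0857 with estimated correlation. Fatty acid oxidation genes were lower: 10 of 22 members were lower and 12 were not called (13 were lower over the list alone), with median -0.84, adjusted p = 9.4e-08, or 0.113 with estimated correlation. Acadl, the long-chain acyl-CoA dehydrogenase, was 983 ± 207 with pioglitazone and 160.2 ± 21.004 with CL316243 (-2.44, adjusted p = 5.5e-06). PPAR target genes were lower (1 of 25 members were higher, 10 were lower and 14 were not called, 3 and 11 over the list alone, with median -0.77, adjusted p = 7.4e-04, or 0.256 with estimated correlation). Ucp1 was 1268 ± 271 with pioglitazone and 61.3 ± 1.12 with CL316243 (-3.92, adjusted p = 3.3e-04). MHC class II genes were higher: 5 of 13 members were higher and 8 were not called (5 were higher over the list alone), with median 0.81, adjusted p = 3.2e-05, or 0.151 with estimated correlation. H2-Aa was 562 ± 101.5 with pioglitazone and 4164 ± 15.97 with CL316243 (2.85, adjusted p = 5.5e-06). Saa3 was 206 ± 117 with pioglitazone and 3151 ± 234 with CL316243 (3.93, adjusted p = 4.1e-06). Neutrophil markers were higher with CL316243 (median 0.62, adjusted p = 0.00255, or 0.256 with estimated correlation), as were T and NK cell markers (median 0.57, adjusted p = 0.0174, or 0.422 with estimated correlation). With the Slc39a1 set as a covariate their medians were -0.0868 and -0.00820, and both calls ended. limma called 942 probe sets, 361 higher and 581 lower. All these arrays were earlier ones, and the count was 1118 with a batch block, 1735 on earlier arrays alone, 1969 without the doubted arrays and 136 with that covariate, which also parts these groups. Others gave 3086 with array weights, 2543 with compared groups only and 391 with a scan day block. The 3' to 5' ratio did not overlap, at 1.52 to 1.53 with CL316243 and 0.105 to 0.558 with pioglitazone for Actb and 0.998 to 1.11 and 0.743 to 0.857 for Gapdh. The count was 276 without CL316243 replicate 2, 277 without CL316243 replicate 1, 542 without treated ob/ob replicate 1 and 581 without treated ob/ob replicate 3.

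The log2 fold changes of 11 pairs of comparisons were correlated across 12422 probe sets, which are not independent replicates. The obesity models of the males shared their called genes: 140 probe sets rose in both against 8.54 if independent, and 75 fell in both against 3.87. Their Pearson r was 0.708, against a mean of 0.448 in 100 simulations of unchanged groups that share the lean arrays and 0.518 with these split. For ob/ob and Ay/+ females 349 probe sets rose in both against 80.3 if independent, and 625 fell in both against 201, with r of 0.534, 0.504 simulated and 0.354 split. The ob/ob effects in females and males share no array: 400 probe sets rose in both against 72.1 if independent, and 245 fell in both against 86.4, with 35 and 10 in opposite directions against 63.6 and 97.9, and r of 0.412. With pioglitazone in Ay/+ and ob/ob females 62 probe sets rose in both against 1.93 if independent, and 22 fell in both against 0.373 (r of 0.377). In Ay/+ females and diet-induced obese males 68 rose in both against 2.00, and 28 fell against 0.746 (r of 0.305). In ob/ob females and those males 42 rose in both against 0.689, and 18 fell against 0.271 (r of 0.265). Where pairs share untreated arrays, the counts if independent leave the sharing out and are not the value of no change. Of the probe sets lower in Ay/+ than lean females, 114 rose with pioglitazone against 30.4 if independent, and of those higher 52 fell against 7.07. The r of -0.360 was -0.0804 with the shared arrays split and -0.441 simulated. For ob/ob females and pioglitazone these were 45 against 12.8 and 16 against 4.23 (r of -0.0237, -0.433 simulated, 0.0747 split), and for ob/ob females and CL316243 60 against 27.1 and 115 against 28.0 (r of -0.396, -0.375 simulated, -0.222 split). For diet-induced obesity and pioglitazone they were 6 against 0.590 and 18 against 1.003 (r of -0.436, -0.563 simulated; 3 shared arrays are too few to split). Pioglitazone and CL316243 in ob/ob females had an r of 0.0168 (0.347 simulated, -0.150 split), and 9 probe sets rose with both against 1.41. Simulated r above are means, and only the r of 0.377 lay outside the range of its 100 simulations. The covariance lay outside in 5 of the 11 pairs: ob/ob with Ay/+ females (0.194 above the simulated mean), ob/ob with diet-induced obese males (0.128), ob/ob females with ob/ob males (0.167), pioglitazone in Ay/+ with ob/ob females (0.0591) and ob/ob females with CL316243 (-0.118).

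Over all comparisons, camera with its preset correlation called 150 of 448 list tests, and 38 held with an estimated one. Only the preset p is given above for these 38. In ob/ob females these were the macrophage, lysosome, de novo lipogenesis, oxidative phosphorylation and immediate early lists. In ob/ob males they were the macrophage, lysosome, cytokine, adipocyte, de novo lipogenesis, TCA cycle, cell cycle and endothelial lists. In diet-induced obese males the macrophage, cytokine, de novo lipogenesis, TCA cycle, cell cycle and endothelial lists held, and between ob/ob and diet-induced obese males the adipocyte list. With pioglitazone the PPAR target, oxidative phosphorylation, TCA cycle, fatty acid oxidation and thermogenic lists held in all 3 models, with extracellular matrix in Ay/+ females and MHC class II and cytokines in diet-induced obese males. fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, called 151 of the 448, and its mixed test of change in either direction called 222.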

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

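The tests of the CL316243 genes, of the batch for the adipocyte markers and of swapped labels were chosen after the results were seen; the others of this part were chosen before.

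The 5 highest genes with CL316243 (Slc39a1, Sdc4, Kdelr2, Gnb1, Ap2a2; median log2 fold change 3.67) were weighed first. Their median range within the 4 untreated Ay/+ females was 4.05, but 0.27 without the doubted replicate 1, and 2.53 within the lean males. All 5 belong to the Slc39a1 set of 52, of which 12, these 5 among them, stay above r of 0.8 without the doubted arrays. Whether a shared movement within groups explains them is open. The Ay/+ range rests on 1 array. Earlier arrays were the higher ones in lean males, the later one in ob/ob females. Means of the 5 genes above the highest untreated ob/ob female were found on 8 of 33 arrays without the drug, but these were Ay/+ females and males, which do not show what raised them in ob/ob females. There the treated arrays lay at 12.07 or above against 9.84 at most without the drug, so CL316243 as the source stays open, as do the scan day and, without replicate 4, RNA quality, which go with it, and what moves the set was not tested.

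Adipocyte markers had a median ob/ob effect in males minus females of -0.87. A scanner ceiling for bright probe sets on the earlier arrays would leave dim members nearer 0, and the 7 members under a deposited signal of 10000 had a median of -1.20 (95% bootstrap interval -2.06 to -0.31), whose upper end lies nearer 0 than -0.44, so too few dim members keep it open. The batch could contribute: the median was -0.73 with the batch as a block and -0.19 within the later arrays, where lean and ob/ob females have 1 array each, too few to tell batch and effect apart. A difference between the sexes stays open, as untested.

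Ay/+ female replicate 1 and ob/ob female replicate 4 stood far from their groups (r of 0.872 and 0.877). A swap of these labels is excluded by the agouti gene, at 379 on Ay/+ replicate 1 and 13.8 on ob/ob replicate 4. The latter lies below the pseudocount, so the ratio of 27.4 is inexact, but at least 16.5 with that floor. The later batch, to which both belong, is argued against as the whole cause: r between arrays fell across batches by 0.0649 and 0.1004 in these groups and by at most 0.0162 in the other groups that hold both. A different animal, dissection or tissue composition may lie behind these arrays, and none of these was tested.

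In 12 of 198 tests of groups of 4 an array stood apart from the others by the gap to its neighbour over the range (the Dixon test at 0.05), where chance gives 9.9, or 1 in 20. For Ay/+ female replicate 1 these were endothelial markers, 8.56 against 7.66 to 7.75 (0.897), thermogenic genes, 5.82 against 6.33 to 6.43 (0.835) and the percent of probe sets at or above the pseudocount, 72.7 against 79.4 to 79.9 (0.937). For ob/ob female replicate 4 they were Pparg, 8.03 against 9.13 to 9.31 (0.859), Cd68, 10.00 against 11.83 to 12.09 (0.875) and oxidative phosphorylation genes, 9.81 against 9.55 to 9.56 (0.963). For ob/ob male replicate 1 they were mesothelial and epithelial markers, 7.52 against 6.09 to 6.28 (0.867) and male reproductive tract markers, 7.77 against 5.53 to 5.67 (0.936). The others were macrophage markers on pioglitazone-treated diet-induced obese male replicate 2, 8.84 against 9.26 to 9.33 (0.868); thermogenic genes on replicate 3 of that group, 7.09 against 6.71 to 6.73 (0.942); Cidea on lean female replicate 1, 9.93 against 11.16 to 11.34 (0.874); and pancreas genes on lean female replicate 2, 6.08 against 6.397 to 6.46 (0.833).

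The ob/ob effect differed between the sexes for 706 probe sets, among them Pparg -1.20 (adjusted p = 0.0215), Slc2a4 -2.06 (adjusted p = 8.5e-04), Ucp1 4.17 (adjusted p = 5.7e-04), Cidea 3.02 (adjusted p = 3.4e-04), Cox8b 2.40 (adjusted p = 5.0e-04) and Cox7a1 2.72 (adjusted p = 0.00118). Ucp1 lay below the pseudocount in lean and ob/ob males, so its difference is set by that floor and does not show that the sexes differ. The call of Pparg ended without 1 array. Its adjusted p was 0.0596 without lean female replicate 3 and 0.0533, 0.0591 or 0.0600 without ob/ob female replicate 1, 2 or 3. The pioglitazone effect differed between ob/ob and Ay/+ females for 3.

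Other groupings of the same arrays were refitted, 35 for a comparison of 2 groups and 100 draws for a difference of effects. The real grouping alone reached its count (the highest other follows it) for ob/ob against lean females (3025, 2593) and Ay/+ against lean females (2207, 2177). It did so for ob/ob against lean males (1314, 30), diet-induced obesity (230, 44) and pioglitazone in ob/ob females (132, 50). It also did for pioglitazone in diet-induced obese males (176, 45), lean males against females (1948, 160) and ob/ob against diet-induced obese males (109, 21). For the ob/ob effect between the sexes these were 706 and 143. That alone does not exclude chance: 35 groupings allow no share below 1 in 35, and Ay/+ females led narrowly. For the pioglitazone effect between ob/ob and Ay/+ females 4 of 100 draws gave as many, with 3 against a highest other of 16. That share is under 0.05, yet chance cannot be firmly excluded: 626 probe sets had an unadjusted p under 0.05, where chance gives 621, and the count was 0 without any 1 of 3 arrays. What gave the 16 was not tested. For pioglitazone in Ay/+ females 4 of 35 gave as many (377 against a highest other of 1202), and for ob/ob against Ay/+ females 2 of 35 (2686 against a highest other of 4073), so chance cannot be excluded by this count. The highest other groupings of the first 2 put ob/ob female replicate 4 or Ay/+ female replicate 1 with lean replicates 1 to 3. Those of the last 2 put Ay/+ female replicate 1 with the treated arrays, or exchanged it with ob/ob female replicate 4, which points to a structure of the samples set by these 2 arrays. On earlier arrays, which hold neither, the counts were 1221 and 4745. Regrouping does not part an effect from the scan day, which no compared groups share for pioglitazone in ob/ob females or ob/ob against lean males, and with scan day as a random block their counts were 56 and 1076. The comparisons with 2 CL316243 arrays were not tested in this way.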

How the results depend on the processing

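Earlier or later arrays only, scan day as a random block, leaving out the 4 doubted arrays and the Slc39a1 set covariate were chosen after the data were seen. The counts called were ob/ob females 3025, Ay/+ females 2207, ob/ob males 1314, diet-induced obesity 230, pioglitazone in Ay/+ 377, pioglitazone in ob/ob 132, pioglitazone in diet-induced obesity 176, CL316243 464, lean sexes 1948, ob/ob effect between sexes 706, ob/ob against Ay/+ 2686, ob/ob against diet-induced obesity 109, pioglitazone between models 3, CL316243 against pioglitazone 942. With quantile normalization, a pseudocount of 1, no trend and the batch as a fixed block every count stayed within 1.5 times its value. The named genes (293 cases, only part given here) kept direction and side of the threshold in 282 with quantile normalization, 289 with a pseudocount of 1, 289 without a trend and 290 with the batch as a block, and the called list tests in 134, 143, 150 and 145 of 150. For genes it was 277 of 277 above the median of mean log2, 287 of 293 with the replicate block, 285 with array weights, 249 with the compared groups only, 267 with scan day as a random block, 264 with the Slc39a1 set as a covariate and 285 without the doubted arrays. On earlier arrays it was 219 of 236, and on later arrays 128 of 201, with 3 reversed. For lists these were 89 of 114 and 71 of 100, with 10 reversed. Signal near the background limits dim genes, since the pseudocount of 23 holds their fold changes down.

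With array weights the counts that moved were ob/ob females 5630, ob/ob males 2554, diet-induced obesity 631, pioglitazone in Ay/+ 641, pioglitazone in ob/ob 699, pioglitazone in diet-induced obesity 570, CL316243 3186, lean sexes 3593, ob/ob effect between sexes 3988, ob/ob against Ay/+ 5352, ob/ob against diet-induced obesity 599, pioglitazone between models 55, CL316243 against pioglitazone 3086. With the compared groups only the counts that moved were ob/ob females 1406, Ay/+ females 440, ob/ob males 2005, pioglitazone in Ay/+ 90, pioglitazone in ob/ob 14, pioglitazone in diet-induced obesity 73, CL316243 20, ob/ob against Ay/+ 225, ob/ob against diet-induced obesity 185, pioglitazone between models 1, CL316243 against pioglitazone 2543. With the probe sets above the median of mean log2 the counts that moved were lean sexes 1251, ob/ob against diet-induced obesity 196. With scan day as a random block the counts that moved were ob/ob females 1451, Ay/+ females 1328, pioglitazone in ob/ob 56, CL316243 32, lean sexes 1039, ob/ob effect between sexes 237, ob/ob against Ay/+ 1309, CL316243 against pioglitazone 391. On earlier arrays only the counts that moved were Ay/+ females 3573, pioglitazone in Ay/+ 1221, pioglitazone in diet-induced obesity 59, CL316243 1714, ob/ob against Ay/+ 4745, pioglitazone between models 46, CL316243 against pioglitazone 1735. On later arrays only the counts that moved were ob/ob females 517, Ay/+ females 162, diet-induced obesity 69, pioglitazone in diet-induced obesity 69, lean sexes 395, ob/ob effect between sexes 226, ob/ob against Ay/+ 244, ob/ob against diet-induced obesity 17. Without the 4 doubted arrays the counts that moved were ob/ob females 4869, Ay/+ females 4102, diet-induced obesity 497, pioglitazone in Ay/+ 1095, pioglitazone in diet-induced obesity 352, CL316243 1982, lean sexes 3345, ob/ob effect between sexes 2642, ob/ob against Ay/+ 5357, ob/ob against diet-induced obesity 457, pioglitazone between models 30, CL316243 against pioglitazone 1969. With the Slc39a1 set as a covariate the counts that moved were Ay/+ females 1268, CL316243 6, ob/ob effect between sexes 1497, ob/ob against Ay/+ 311, CL316243 against pioglitazone 136. List tests called fell from 150 to 38 when only the preset correlation was replaced by an estimate. Why the counts moved was not tested.

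The genes and the lists whose test turned its direction were, with a list's median, on later arrays only, Pcx in ob/ob effect between sexes 0.025, Cd68 in ob/ob against Ay/+ -0.0222, Adipoq in ob/ob against Ay/+ 0.27, skeletal muscle in ob/ob females 0.0866, neutrophil markers in Ay/+ females -0.60, pancreas in Ay/+ females -0.38, lysosome in ob/ob effect between sexes 0.25, fatty acid oxidation in ob/ob effect between sexes 0.28, skeletal muscle in ob/ob effect between sexes -0.25, T and NK cell markers in ob/ob against Ay/+ 0.25, ovary and uterus in ob/ob against Ay/+ 0.15, pancreas in ob/ob against Ay/+ 0.14, unfolded protein response in ob/ob against Ay/+ 0.0649; without the 4 doubted arrays, macrophage and myeloid markers in pioglitazone between models -0.00140, lysosome in pioglitazone between models -0.0634; and with array weights, lysosome in pioglitazone between models -0.0158. The unfolded protein response median kept its sign. Medians of other called lists changed sign with the test direction kept: on later arrays only, cell cycle in ob/ob females -0.0457, adipocyte markers in Ay/+ females -0.21, adipocyte markers in lean sexes -0.0409; with quantile normalization, adipocyte markers in Ay/+ females -0.0261; with the Slc39a1 set as a covariate, neutrophil markers in Ay/+ females -0.14, T and NK cell markers in CL316243 against pioglitazone -0.00820, neutrophil markers in CL316243 against pioglitazone -0.0868; on earlier arrays only, immediate early genes in diet-induced obesity -0.0654, lysosome in pioglitazone between models -0.0440. The adipocyte median with pioglitazone in ob/ob, -0.0149, ran from 0.0473 to 0.27 in 7 settings. Lean, Ay/+ and ob/ob females have 1 later array each, so their changes of sign on later arrays rest on single arrays. The cause was not tested.

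Leaving out 1 array gave ob/ob females 1912 to 3984, Ay/+ females 1459 to 3383, ob/ob males 1030 to 1219, diet-induced obesity 117 to 181, pioglitazone in Ay/+ 224 to 880, pioglitazone in ob/ob 44 to 141, pioglitazone in diet-induced obesity 111 to 160, CL316243 4 to 1261, lean sexes 726 to 2333, ob/ob effect between sexes 418 to 1671, ob/ob against Ay/+ 1494 to 4332, ob/ob against diet-induced obesity 39 to 153, pioglitazone between models 0 to 9, CL316243 against pioglitazone 276 to 651, list tests called 136 to 156 and named genes called 247 to 268; with 1 CL316243 array left, it is assumed to vary like the other groups. Earlier arrays hold no ob/ob males and later arrays no drug-treated females, so those comparisons gave no value there.

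The replicate numbers do not pair the arrays: in 39 pairs the r of deviations from the group means ran from -0.30 to 0.19, with a median of 0.00110, and 3 were above 0.1. With the replicate block the counts were ob/ob females 3006, Ay/+ females 2161, ob/ob males 1292, diet-induced obesity 207, pioglitazone in Ay/+ 312, pioglitazone in ob/ob 95, pioglitazone in diet-induced obesity 167, CL316243 477, lean sexes 1942, ob/ob effect between sexes 691, ob/ob against Ay/+ 2689, ob/ob against diet-induced obesity 99, pioglitazone between models 2, CL316243 against pioglitazone 870, with 151 list tests and 261 named genes called.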

Other observations

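Genes of antioxidant defence and glutathione moved both ways in obesity, and their list test was not passed. Of 30 measured members, 7 rose and 10 fell (8 and 16 adjusted over the list alone) in ob/ob females (adjusted p = 0.473), 3 rose and 10 fell (4 and 10 adjusted over the list alone) in Ay/+ females (adjusted p = 0.481) and 3 rose and 5 fell (4 and 7 adjusted over the list alone) in ob/ob males (adjusted p = 0.367). Sod3, the extracellular superoxide dismutase, rose in Ay/+ females from 657 ± 62.8 to 5259 ± 2274 (log2 fold change 2.82, adjusted p = 1.6e-07). Gsta4, a glutathione transferase of lipid aldehydes, fell from 822 ± 725 to 62.2 ± 36.4 (log2 fold change -2.84, adjusted p = 0.00604). Insulin signalling genes also moved both ways, with 5 of 19 higher and 3 lower in ob/ob females (5 and 3 adjusted over the list alone; adjusted p = 0.961). Their lowest adjusted p in camera was 0.0512, in ob/ob against lean males.

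Other lists passed the test in none of the 14 comparisons, at these lowest adjusted p in limma's camera: clock genes 0.160, mesothelial and epithelial markers 0.142, male reproductive tract 0.110, antioxidant and glutathione genes 0.367 and Y-linked and X-inactivation genes 0.354.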
